A study of Bombyx mori with 12 samples.

How the data were processed

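Transcript levels were measured in the silkworm Bombyx mori with a custom Agilent oligonucleotide array, hybridised in 1 colour with Cy3-labelled RNA. The series holds 12 arrays. The corpora cardiaca-corpora allata complex (CC-CA) is the paired gland behind the larval brain in which the corpora allata make juvenile hormone and the corpora cardiaca store and release neurohormones. It was dissected on day 2 of the 4th instar in 2 batches that the labels call independent experiments, and on day 4 of the 5th instar in 1 sample. The 9 other tissues had 1 array each. Prothoracic gland, brain, fat body, midgut, epidermis, Malpighian tubule and salivary gland came from day 2 of the 4th instar, and testis and ovary from day 10 of the 5th instar, 3 days after wandering began. Larvae of a commercial hybrid strain were fed mulberry leaves. RNA was purified on spin columns, then amplified linearly and labelled, per the labels' protocols.

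The deposited scanner files hold spot intensities. Per the file headers, each array was scanned at high and low gain and the scans were combined, and Agilent Feature Extraction 9.5.3.1 subtracted the background and replaced dim values by a small positive surrogate. This processed intensity was not normalised between arrays. The deposited table of processed values holds intensity on a linear scale as well. Each of its columns equals the processed signal of its array divided by 1 constant, which lay between the 28.7 and 32.9 percentile of the probes of that array. What the constant stands for, and so how the columns were centred against each other, is not given in the sources used here. The medians of its columns were 9.43 and 9.61 for the 4th instar CC-CA, 10.1 for the 5th instar CC-CA, 8.45 for prothoracic gland, 7.11 for brain, 6.54 for fat body, 6.56 for midgut, 7.18 for epidermis, 7.91 for Malpighian tubule, 9.18 for salivary gland, 4.95 for testis and 6.94 for ovary.

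Each array carried 45220 spots, of which 43803 were not controls. For the analysis, log2 of the processed signal was taken and the array's 75th percentile over non-control spots was subtracted. Spots marked as outliers were left out, spots of 1 probe were averaged, and the 224 of 42564 probes that lacked a value on any array were dropped. The 75th percentile of the processed signal ranged from 1402 in fat body to 5827 in ovary, and the share of spots well above background from 60.4% in fat body to 78.6% in testis. The number of arrays limits the precision.

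A probe entered the tissue comparisons where it was well above background on every array of at least 1 group (38131 probes), and the stage comparison where it was so on both 4th instar arrays or on the 5th instar array (32125 probes). Where a probe was not well above background in the dimmer group, the fold of a named gene is given as a bound, written "at least N-fold". Medians of sets and lists, counts of calls and fitted log2 differences used such signals without a bound, except where a floor is stated. The bound sets the mean of the brighter group against, on each dim array, the higher of the lowest signal well above background and the probe's own signal.

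The fits used limma 3.58.1 in R 4.3.3, with data.table version 1.17.8, and the plots were drawn with matplotlib 3.10.9. The group fit gave each of the 11 groups a mean over all 12 arrays. Its only residual degree of freedom came from the 2 CC-CA arrays of the 4th instar, and empirical Bayes moderation added a prior worth 7.41 degrees of freedom. Each single array was therefore assumed to vary like that pair. A probe was called enriched where limma's Benjamini-Hochberg adjusted p was below 0.05 and the log2 difference at least 1 against every one of the 9 tissues. The stage comparison subtracted the 5th instar CC-CA from the mean of the 4th instar pair. A further fit set all 3 CC-CA arrays against the 9 other arrays (10 residual degrees of freedom). Its spread was mainly that between tissues, with a part from the CC-CA arrays themselves. Gene lists were tested in that fit with camera, at a preset correlation of 0.01 and with an estimated one. The fit counted the 3 arrays of 1 tissue as independent, so its p-values, those of camera included, overstate the certainty about tissues.

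The arrays lay on 3 slides of 4. Slide 1 held the CC-CA replicate 1, prothoracic gland, brain and fat body. Slide 2 held the CC-CA replicate 2, the 5th instar CC-CA, midgut and salivary gland. Slide 3 held epidermis, Malpighian tubule, testis and ovary. A group fit with slide as a block had 0 residual degrees of freedom left, so stage differences were also taken within slide 2. Slide 3 held no CC-CA array, so for epidermis, Malpighian tubule, testis and ovary the tissue and the slide cannot be told apart.

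The array names most sequences by clone or gene model identifiers. Of 32372 sequence names, 416 carried a gene name for 345 genes, and all 6 full transcript accessions were found in the RefSeq gene table. A gene was represented by its probe with the highest mean over all arrays. Of 20 gene lists, 6 had named members on the array, covering juvenile hormone synthesis, juvenile hormone degradation and transport, hormone-response transcription factors, neuropeptides and hormones, hormone and neuropeptide receptors, and cuticular proteins. The other 14 lists had no named member, among them the marker lists for salivary gland, midgut, fat body, neurons and ribosomal proteins. Named in the text are the members of the juvenile hormone lists above background on a CC-CA array (at most the 12 with the highest CC-CA level per list), the 10 genes with the largest margin over the other tissues, the 10 largest fitted rises and 10 largest fitted falls between stages, up to 4 called members of each other list, the 5 largest fitted differences of the 3 CC-CA arrays against 9, and up to 2 of the genes with the largest margin for each other tissue. Genes named outside that rule were chosen after their values were seen, and are identified as such. Kr-h1 is named as the only measured member of its list. Groups, gene lists, the tests of these comparisons and the naming rule were fixed before the data were examined. The sets of sequences abundant in 1 tissue only were defined afterwards.

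The fits were tested on simulated data in which 50 probes were changed at each size. Of probes raised in the CC-CA alone, the enriched call recovered 0% at a log2 change of 2, 4% at 3, 74% at 4 and 94% at 5. The stage comparison recovered 0%, 52%, 90% and 98% at those sizes, with 7 unchanged probes called higher and 12 called lower. The comparison of 3 arrays against 9 recovered 88%, 98%, 100% and 100%, in a simulation that left out the spread between tissues. The rates for the enriched call and the stage comparison do not carry over to the data, where far more probes differed. At least 6497 differed from each tissue, and 1443 were called higher and 404 lower between stages. In the data BmorCPH12 was called enriched at a log2 margin of 1.86, so the 0% at 2 for the enriched call sets no limit for the data. Alternatives covered the background correction, the scaling between arrays, the deposited value table, filters and floors for dim probes, the variance model, the fold threshold, the arrays included and the slide. A background correction with normexp on the mean spot signal had been planned, but the files used here gave the median signal, so the correction was run on that. It was chosen after seeing the data, as were the comparisons without the largest clone set, without testis, and without probes 4-fold higher in another tissue.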

Results

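Transcript profiles of the CC-CA of Bombyx mori larvae were recorded on 12 arrays, alongside profiles of 9 other tissues. The CC-CA of day 2 of the 4th instar was represented by 2 arrays from independent experiments. The CC-CA of day 4 of the 5th instar and each other tissue were represented by 1 array, so these groups had no replicate of their own. Signals are log2 values relative to the 75th percentile of each array. The 2 CC-CA arrays of the 4th instar correlated at r = 0.980 across probes, and with the 5th instar CC-CA at 0.952 and 0.965. Correlations among the other 9 tissues ran from 0.711 to 0.917. These correlations are across probes of single arrays, and probes are not independent replicates. The median absolute difference between the replicate CC-CA arrays was 0.43 on the log2 scale.

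The first comparison asked which transcripts the juvenile hormone gland held above all other tissues. Jhamt, which encodes the methyltransferase that acts late in juvenile hormone synthesis, was among the 4 named genes far above all other tissues, with AKH1, AKH2 and pburs. Its log2 level was 2.24 ± 0.21 (SD, n = 2) in the 4th instar CC-CA, and none of the 9 other tissues was well above background, which put the CC-CA at least 153-fold higher than fat body, the tissue that set the bound. The adipokinetic hormones, peptides made in the corpora cardiaca that mobilise energy stores, were high there. AKH1 reached 5.30 ± 0.11 and AKH2 5.30 ± 0.33 (SD, n = 2), 384-fold above ovary and 351-fold above brain, the next highest tissues. Transcripts of pburs, the partner subunit of the tanning hormone bursicon, stood at 2.56 ± 0.16 (SD, n = 2), at least 191-fold above the bound set by fat body. Only testis of the 9 tissues was well above background, at -6.29.

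Of the 31 neuropeptide and hormone genes measured, these 3 (AKH1, AKH2 and pburs) were enriched, and the same number were enriched when adjusted over the list alone. Of the 11 other members well above background on both 4th instar arrays, 8 had their highest level in brain and 2 in testis. Corazonin was 3.20 in brain against -2.05 ± 0.03 in the 4th instar CC-CA, and allatostatin A was 2.90 against -4.70 ± 0.01 (SD, n = 2), values chosen after they were seen. Among 37 measured receptors of neuropeptides and hormones, 2 were enriched, as they were when adjusted over the list alone. The receptor transcript BNGR-A2 was 4.92-fold above epidermis, and BNGR-A6-A was at least 2.02-fold above the bound set by fat body. Both receptors were enriched on all 4 of their probes, but BNGR-A6-A lost its call with a floor under dim signals (log2 1.01, adjusted p = 0.201) and with normexp (0.68, adjusted p = 0.145).

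Cuticular protein genes, whose products build the exoskeleton, gave 4 enriched members of 175 measured, and 4 when adjusted over the list alone. BmorCPH27 reached 4.26 ± 0.40 (SD, n = 2) in the CC-CA and was 8.18-fold above salivary gland. BmorCPR22 was at least 4.05-fold above the bound set by fat body, BmorCPH14 was 4.26-fold and BmorCPH12 was 3.64-fold above epidermis. BmorCPR35, chosen after its value was seen, passed on 1 probe that was not the gene's representative. None of the 15 measured genes of juvenile hormone degradation and transport was enriched, on either adjustment. The binding protein transcript jhbp-wds30639 stood at 3.30 ± 0.01 (SD, n = 2) in the CC-CA, below 3.93 in midgut. Kr-h1, the transcription factor induced by juvenile hormone, was at -2.87 ± 0.07 (SD, n = 2) and was not enriched. It was the only measured member of its list.

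In all, limma's group fit called 593 of 38131 probes enriched (362 sequence names), of which 491 were at least 4-fold above every tissue. No probe was called lower than in all 9 tissues, and 9 were so at unadjusted p below the same threshold. Only 27 of the enriched probes belong to genes with a name, and the other 566 probes stand for 350 unnamed sequences. Probes of the clone set whose names hold caL were 77.9% of the enriched and 49.3% of the tested probes. Without that set, 117 probes were enriched, with the CC-CA arrays of both stages pooled 256 were, over the probes well above background on all arrays 174 were (132 of them among the 593), and with quantile normalisation 285 were, all of them among the 593. BmorCPH27, BNGR-A6-A, BmorCPR22, BNGR-A2, BmorCPH14 and BmorCPH12 no longer passed then, with largest adjusted p between 0.0506 and 0.186. Since a call required a small spread between replicates on different slides, the calls themselves do not test for a slide effect.

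**Figure D1:**
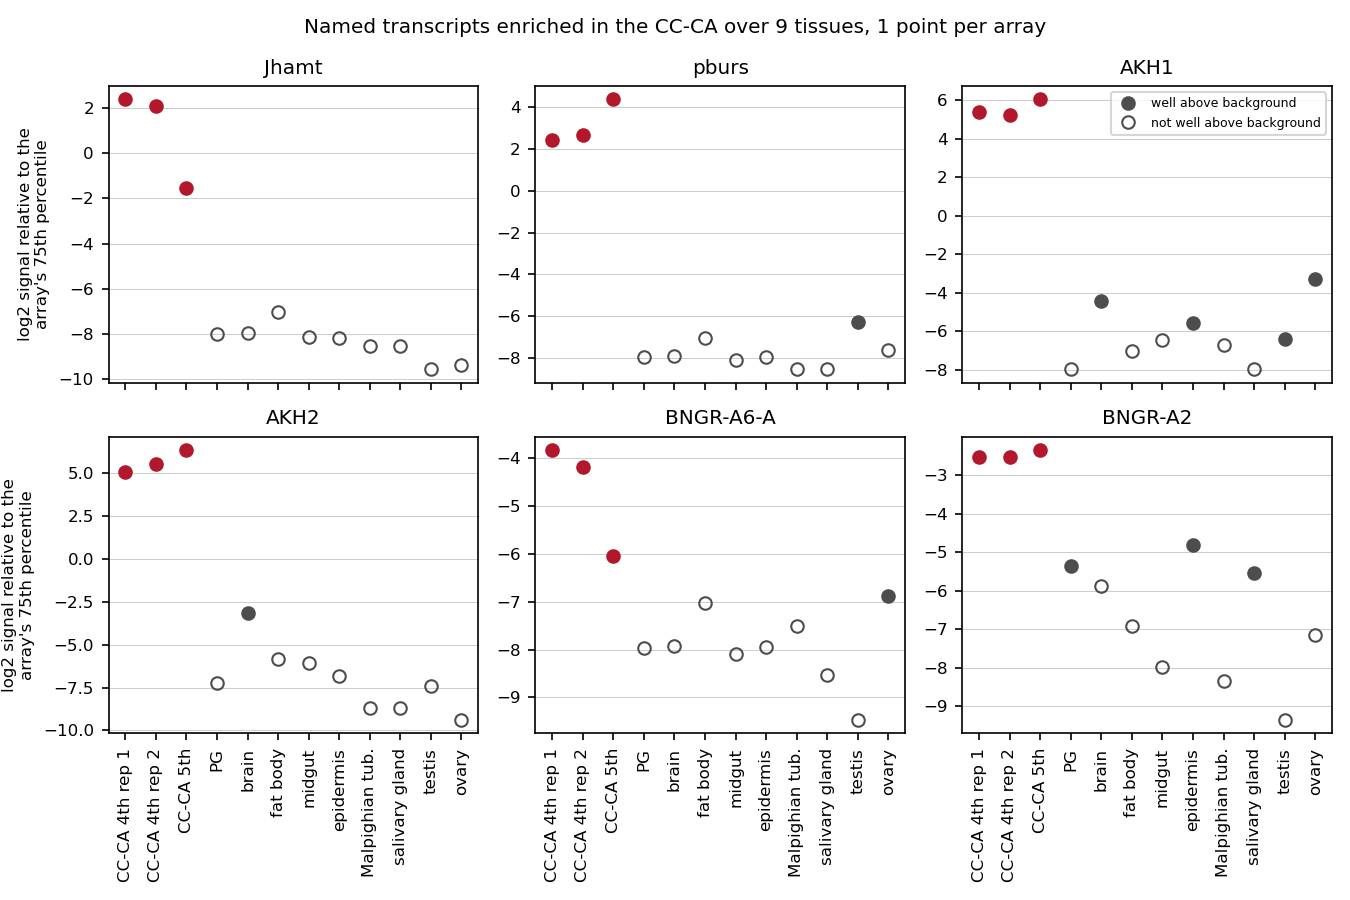
Log2 signal relative to the array's 75th percentile (vertical axis) on each of the 12 arrays (horizontal axis) for the 6 enriched named genes outside the cuticular proteins, 1 point per array, with red for CC-CA and open circles for values not well above background. Jhamt is above background on the 3 CC-CA arrays alone, and AKH1 and AKH2 exceed 5 on each of them.

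A second view set the 4th instar CC-CA against each tissue in turn. As scaled here, prothoracic gland (6497 probes), epidermis (6912) and ovary (7014) differed from it at the fewest probes, and testis (14323) at the most. In the value table prothoracic gland had 4460 higher and 3868 lower, more in all than epidermis, ovary or brain. Against prothoracic gland, 5221 probes were higher and 1276 lower in the CC-CA, and against brain 4622 were higher and 3202 lower. Fat body (4988 higher, 5382 lower) and epidermis (3194 higher, 3718 lower) had more probes lower than higher in the CC-CA. Of their called probes, 51.1% and 55.8% were higher in the value table. For fat body the share was 52.7% with quantile normalisation and 52.5% at a log2 threshold of 2, but 28.3% with a floor under dim signals and 24.9% with normexp. Midgut gave 5971 higher and 4537 lower, Malpighian tubule 6211 and 4105, salivary gland 6342 and 2688, testis 7295 and 7028, and ovary 4158 and 2856. These splits moved with the scaling. The share of called probes that were higher in the CC-CA went in the deposited value table from 80.4% to 53.6% for prothoracic gland, from 60.2% to 48.3% for Malpighian tubule, from 70.2% to 31.2% for salivary gland, from 50.9% to 80.4% for testis and from 59.3% to 72.0% for ovary. Over the 21952 probes well above background on all arrays, it was 41.8% for prothoracic gland, 41.2% for brain, 37.1% for fat body, 41.8% for midgut, 35.7% for Malpighian tubule, 37.2% for salivary gland and 40.9% for ovary. With normexp it was 42.6% for midgut and 49.8% for Malpighian tubule. Without the clone set named caL it was 49.4% for brain, 33.2% for testis and 46.0% for ovary. For testis it was also 47.7% when scaled on the probes detected on all arrays and 48.8% at a log2 threshold of 2.

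**Figure D2:**
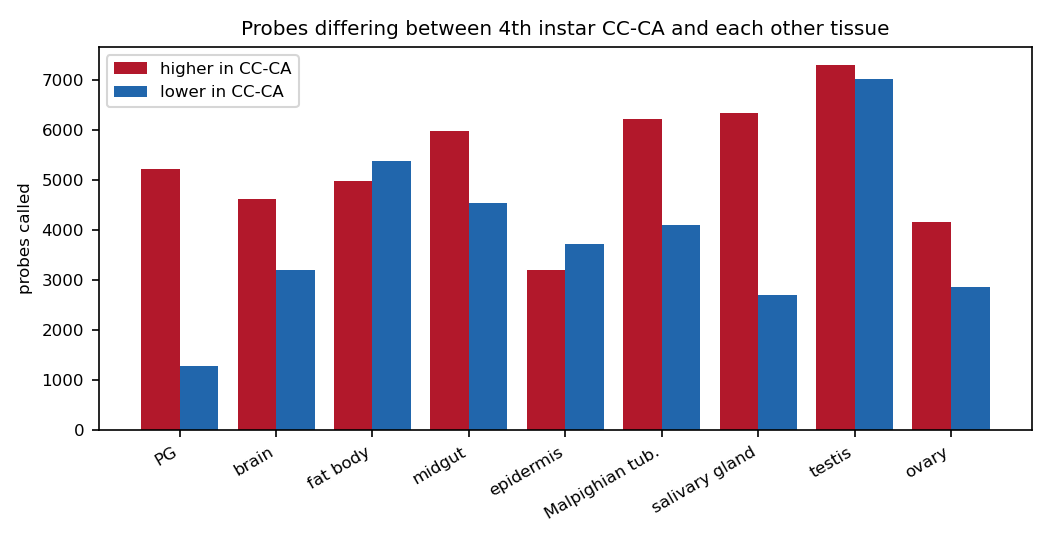
Number of probes (vertical axis) called higher (red) or lower (blue) in the 4th instar CC-CA than in each of the 9 other tissues (horizontal axis), by limma's group fit with a log2 difference of at least 1. Testis has the tallest pair of bars, 7295 and 7028 probes.

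Named genes with large margins in each other tissue are given without a test, and were picked for those margins, so they do not check the labels. In brain these were eclosion hormone at 3.53 and sulfakinin at -0.17, at least 374-fold and 28.8-fold above every other group. Fat body led for AKHR, the receptor of adipokinetic hormone, at 40.8-fold, and for BmorCPG18 at 29.9-fold. Epidermis led for BmorCPR40, at least 1543-fold, and for BmorCPG13 at 832-fold. Midgut held JHEH4, a juvenile hormone epoxide hydrolase, 37.3-fold above the next group, and BNGR-A34 at least 1.61-fold. Malpighian tubule held DHR 117-fold and BNGR-A33 at least 1.76-fold above the rest. Salivary gland led for BmorCPR33 at 33.1-fold and for the binding protein transcript jhbp-brp1649 at 26.1-fold. Testis led for BmorCPR100, at least 18.9-fold. Ovary led for BmorCPR92, at least 80.6-fold, and BmorCPT4, at least 21.2-fold. Prothoracic gland led for BmorCPR8, at least 2.95-fold, and BmorCPR124, at least 1.64-fold.

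The stage comparison set the CC-CA of day 2 of the 4th instar, a stage before a larval moult, against that of day 4 of the 5th instar, the larval instar that ends in metamorphosis. Jhamt was 13.8-fold higher in the 4th instar, a log2 difference of 3.79 ± 0.49 (SE), with adjusted p = 0.00336 (7.83e-11 to 0.186 over the alternatives). That range includes the floor under dim signals, where limma's prior had infinite degrees of freedom and every probe was given the same spread. With quantile normalisation Jhamt was not called, with a similar log2 difference of 3.90 (adjusted p = 0.186), and neither was any other named gene called between stages. It stood at 2.24 ± 0.21 (SD, n = 2) against -1.55, all 4 of its probes were called, and the replicates gave 3.94 and 3.63 above the 5th instar array. The adipokinetic hormones and pburs were not called between stages, with log2 differences of -0.75 for AKH1, -1.04 for AKH2 and -1.80 for pburs (adjusted p = 0.438, 0.298 and 0.0755). Over the alternatives, adjusted p of pburs ran from 0.00865 to 0.198, and it was called in the value table (0.0462), with a variance trend (0.0124), with robust moderation (0.00913) and with normexp (0.00865). Kr-h1 differed by 0.66 ± 0.48 (SE) and was not called.

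Cuticular protein genes held the 10 largest fitted rises and the 10 largest fitted falls of named genes, several of them fitted against signals not well above background and bounded at smaller folds. Of 99 members tested, 32 were higher in the 4th instar and 14 lower, or 38 and 21 adjusted over the list alone. BmorCPG4 was 7.93 ± 0.49 (SE) higher on the log2 scale, BmorCPR41 6.38 ± 0.49 and BmorCPR38 5.84 ± 0.48. BmorCPR28 (5.21), BmorCPG5 (5.37), BmorCPH25 (5.42) and BmorCPH34 (5.17) followed, with bounds of at least 10.5-fold for BmorCPH26 and at least 22.9-fold for BmorCPR21. BmorCPR90 was 7.72 higher, but its replicates differed (log2 10.35 and 5.08 above the 5th instar), and it lost its call with robust moderation too (adjusted p = 0.645). Higher in the 5th instar were BmorCPR72, by -6.42 ± 0.50 (SE) as 4th minus 5th instar, BmorCPH14 by -3.31 ± 0.57, and at least 32.9-fold BmorCPR10. Of a run of numbered family members, BmorCPR107, BmorCPR108, BmorCPR109, BmorCPR110 and BmorCPR111 were all lower in the 4th instar, where none was well above background. Their bounds were at least 4.85-fold, 3.90-fold, 4.35-fold, 7.22-fold and 5.20-fold. BmorCPR122 was at least 10.9-fold and BmorCPG20 at least 6.22-fold higher in the 5th instar. The median over the list was 0.70, above 100% of 10000 random lists of the same size and mean expression, and stayed between 0.40 and 0.84 under the other scalings. The random lists held probes drawn independently, while the correlation among members was estimated at 0.187 in the camera test. The percentile therefore does not measure how certain the shift is. Of the called members, 26 of the 32 higher and 5 of the 14 lower were at least 4-fold more abundant in another tissue than in the CC-CA. Sequences high in epidermis alone other than cuticular genes, 150 of which were tested, had a median of 2.87 in the same comparison.

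**Figure D3:**
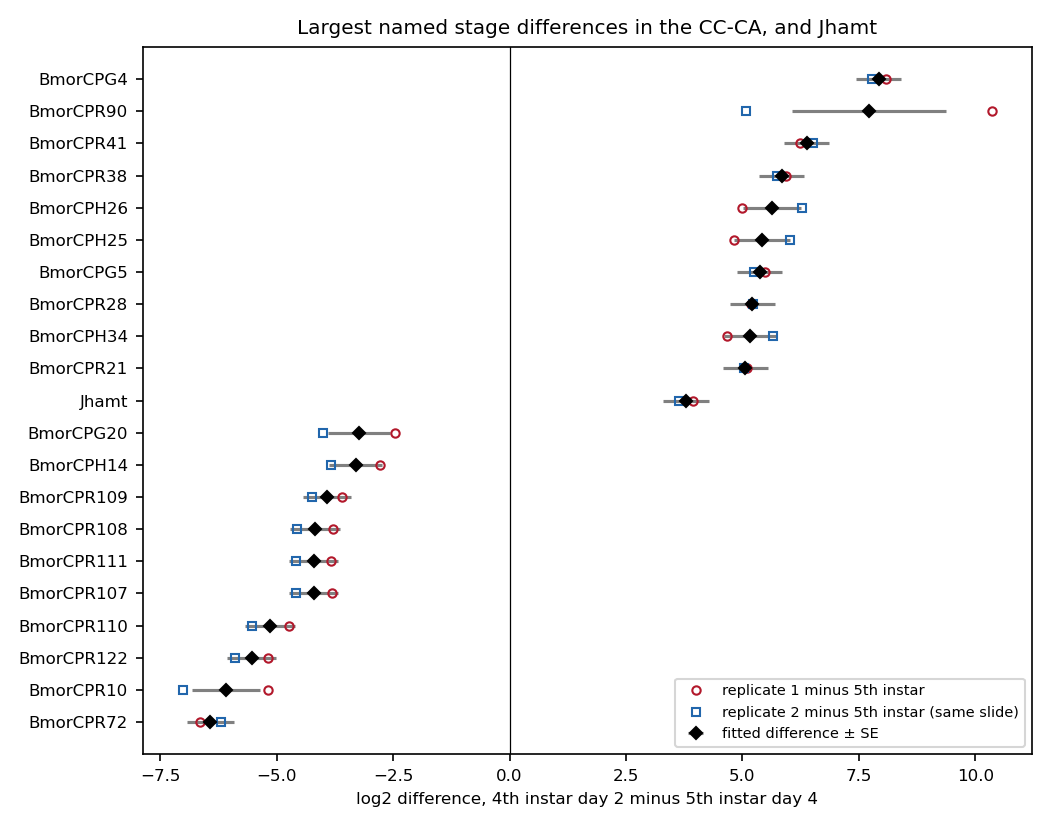
Log2 difference between the 4th and 5th instar CC-CA (horizontal axis, 4th minus 5th) for the 20 named genes with the largest fitted changes and for Jhamt (vertical axis), with diamonds and bars for the fitted difference ± SE, circles for replicate 1 and squares for replicate 2, which shared a slide with the 5th instar array. Genes were chosen to lie on the same side in both replicates, and BmorCPR90 has the widest gap between them, 10.35 against 5.08.

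In the list for juvenile hormone degradation and transport, 5 of 13 tested members were higher in the 4th instar, on either adjustment, and none was lower. The binding protein transcripts jhbp-brp2095, jhbp-an0128 and jhbp-brp1649 were higher by 4.50 ± 0.52, 3.23 ± 0.53 and 2.61 ± 0.49 (SE) on the log2 scale. The other binding protein jhbp-an0921 was at least 4.01-fold higher, and JHEH1, an epoxide hydrolase that inactivates the hormone, at least 3.98-fold. Both of these lost their call in the value table (adjusted p = 0.0727 and 0.0613) and with normexp (0.31 and 0.23). With quantile normalisation all 5 lost theirs (adjusted p = 0.186 for jhbp-brp2095, 0.202 for jhbp-an0128, 0.191 for jhbp-brp1649, 0.2 for jhbp-an0921 and 0.204 for JHEH1). All 5 were at least 4-fold more abundant in another tissue, such as salivary gland for jhbp-an0128 (5.38) and jhbp-brp1649 (3.94) and epidermis for jhbp-brp2095 (4.83). The 31 sequences high in salivary gland alone moved by a median of 2.96. JHE, the juvenile hormone esterase, differed by -1.23, JHEH0 by -0.74, JHEH2 by 1.14, jhbp-an147 by -0.33, jhbp-wds30639 by 0.20, JHEH3 by 0.12, JHEH5 by -0.07 and jhbp-e96h0303 (chosen after its value was seen) by -1.07, none of them called. The probes of JHE, JHEH5 and jhbp-wds30639 disagreed in level. The list's median of 0.20 lay at the 74.7 percentile of random lists and turned to -0.09 in the value table.

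Of the neuropeptide transcripts, 3 were called between stages, all lower in the 4th instar, and 19 were not. SIFamide was called, at -3.14 ± 0.52 (SE, 4th minus 5th instar), and so were NPLP3-like and PTSP, which were not well above background in the 4th instar and at least 1.36-fold and 1.62-fold higher in the 5th. No member of the 22 tested was called higher and 3 were called lower, or 13 adjusted over the list alone. NPLP3-like and PTSP lost their calls with a floor under dim signals (adjusted p = 0.837 and 0.67), with a variance trend (0.235 and 0.0734), and with normexp (0.172 and 0.175). With quantile normalisation all 3 lost theirs (adjusted p = 0.191 for NPLP3-like, 0.186 for PTSP and 0.2 for SIFamide). All 22 had values below 0, and the median of -1.42 lay below all random lists, at percentile 0. The random lists held probes drawn independently, while the correlation among members was estimated at 0.446 in the camera test. Only 14 of the 22 were well above background on both 4th instar arrays. The others entered through the 5th instar array, which favours values below 0. All of the 14 were below 0, with a median of -1.227. The median over all 22 was -0.72 with dim signals set to their floor and reached -1.71 in the value table, with 20 to 22 members below 0 across scalings. Bursicon, at -2.23 ± 0.55 (SE), and myosuppressin, at -1.75 ± 0.49, did not pass over all probes (adjusted p = 0.0551 and 0.0872), and were chosen after their values were seen. Sequences high in brain alone, 97 of which were tested, moved by a median of -1.17 in the same comparison. Of 17 receptors tested none was called, and 1 was adjusted over the list alone. Their median of -0.05, at the 55.5 percentile of random lists, turned to 0.03 when scaled on the probes detected on all arrays and to 0.24 with a floor under dim signals. The 2 called genes outside the lists were also chosen after their values were seen. A polycistronic peptide transcript was at least 7.93-fold higher in the 4th instar, on the 1 of its 2 probes that was tested, and DpHR was 2.84 ± 0.48 (SE) higher.

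**Figure D4:**
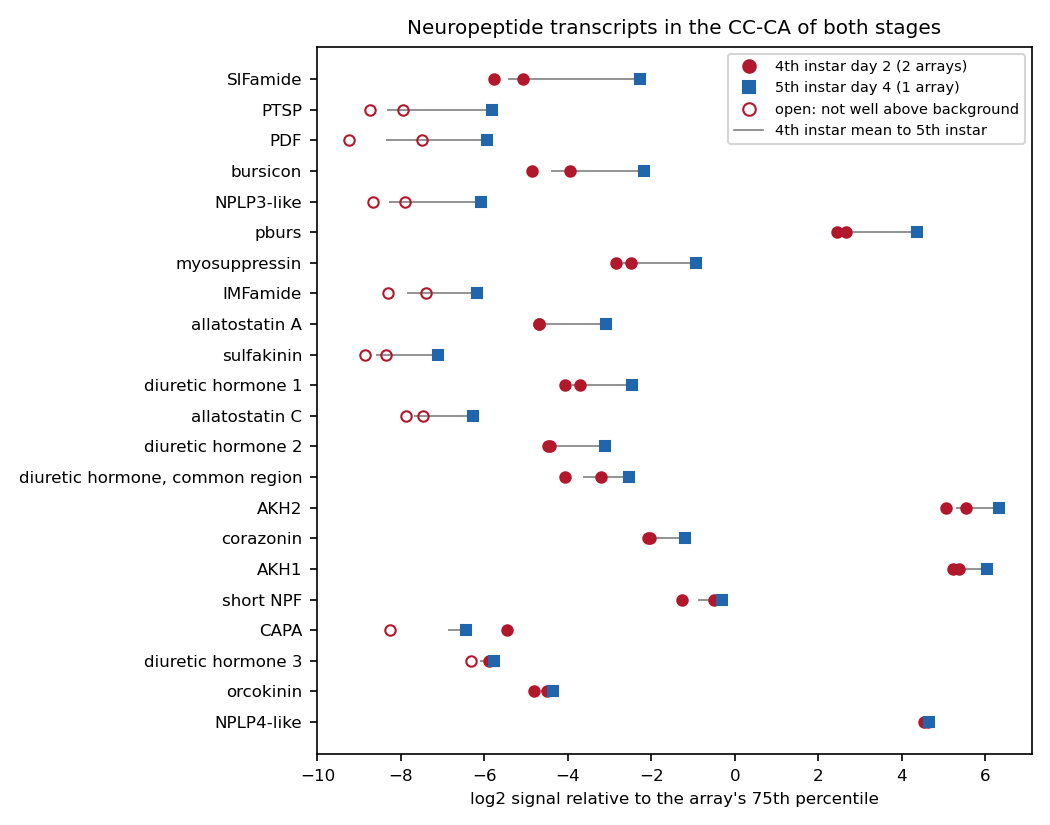
Log2 signal relative to the array's 75th percentile (horizontal axis) of the 22 neuropeptide and hormone transcripts tested between stages (vertical axis), with circles for the 2 arrays of the 4th instar and squares for the array of the 5th instar, open where not well above background, and a grey line from the 4th instar mean to the 5th instar value. The mean of the 4th instar lies to the left of the 5th instar value for all 22 (20 with dim signals set to their floor), with SIFamide at -3.14 as 4th minus 5th instar.

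Transcripts abundant in 1 other tissue only were compared between the CC-CA of both stages, in sets defined after the data were examined. Those of salivary gland (31 tested) had a median of 2.96, those of epidermis 2.99 (175 of 198 tested) and those of midgut 2.84 (112 of 232 tested), with 27, 103 and 51 called higher in the 4th instar and 0, 10 and 0 called lower. With normexp the medians of epidermis and midgut were 1.97 and 1.25. Those of brain had a median of -1.17 (97 of 104 tested, 0 called higher and 1 lower), testis -0.67 (148 of 638 tested, 5 higher and 11 lower), fat body -0.11 (70 of 91 tested, 5 higher and 0 lower) and Malpighian tubule 0.30 (15 of 30 tested, 0 called). Which sequences were tested depended on their CC-CA signal against background, so these medians do not cover the whole sets. For testis the median was -0.16 with a floor under dim signals. For fat body the replicates went apart, with 1.07 for the replicate on the slide of the 5th instar and -1.01 for the other. The direction of fat body turned with normexp (0.10) and with a floor under dim signals (0.24). Of the 1443 probes higher in the 4th instar, 870 were at least 4-fold more abundant in another tissue than in the CC-CA of either stage, against 9206 of 32125 tested. As shares these are 60.3% of the higher probes, 25.0% of the lower ones and 28.7% of those tested. With such probes left out, 463 were called higher and 209 lower.

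**Figure D5:**
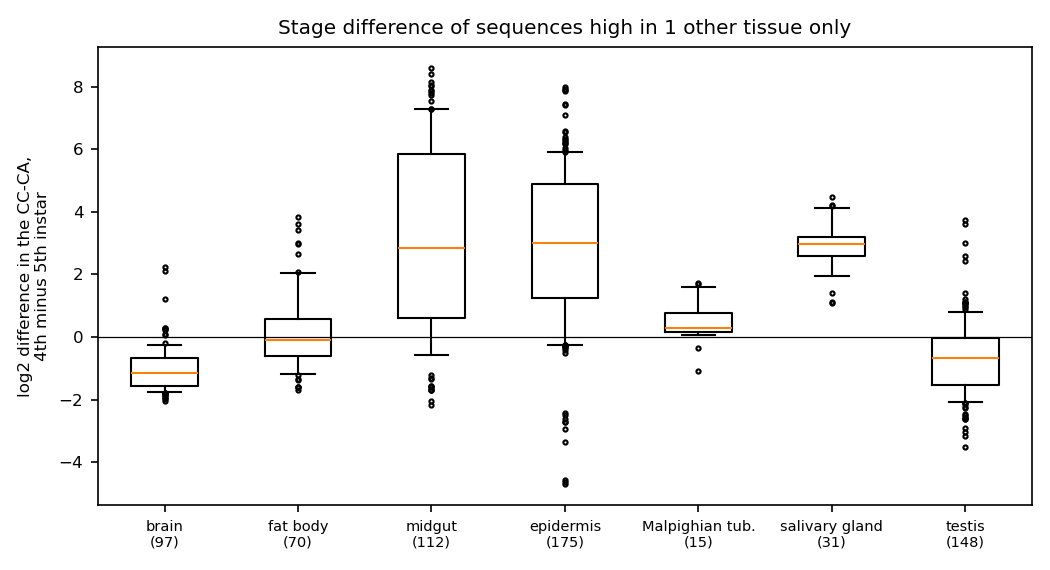
Log2 difference between the 4th and 5th instar CC-CA (vertical axis, 4th minus 5th) of sequences abundant in 1 other tissue only (horizontal axis, number tested in brackets), with boxes for quartiles, lines for medians, whiskers for the 10th to 90th percentile and points beyond them. Medians are near 3 for salivary gland (2.96) and epidermis (2.99), and below 0 for brain (-1.17).

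In limma's group fit, 1443 of 32125 probes were higher and 404 lower in the 4th instar at adjusted p below 0.05, with a median SE of 0.49. With a variance trend the counts were 3162 and 2009 (61.2% higher), and with robust moderation 2423 and 1453 (62.5%). With replicate 2 set against the 5th instar array of the same slide, their medians were 3.00 and -2.83, values that the calling itself favours. The 5th instar had 1 array, assumed to vary like the 4th instar pair, and the call rests on that pair's spread. With quantile normalisation no probe was called in either direction (smallest adjusted p = 0.186). Of the calls, 78.1% were higher in the 4th instar as reported and 65.6% in the value table. Over the probes well above background on all arrays it was 48.9% (1455 higher, 1521 lower). These were mostly other probes, since only 261 of the 1455 were among the 1443 and 46 of the 1521 among the 404.

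The third comparison set all 3 CC-CA arrays against the 9 other tissues, with mainly the spread between tissues as the error. It counted the 3 arrays of 1 tissue as independent, so its p-values, those of camera included, overstate the certainty. AKH2, AKH1, pburs, Jhamt and BmorCPH27 were among 10 named genes called higher, with adjusted p = 2.51e-05, 1.09e-05, 2.79e-07, 1.96e-05 and 0.000918. With dim signals set to their floor, since most tissues were not well above background for the first 4, the log2 differences were 11.67 (AKH2), 11.08 (AKH1), 9.36 (pburs), 7.31 (Jhamt) and 6.13 (BmorCPH27). No named gene was called lower. By list, 3 neuropeptide genes, 2 receptors, 4 cuticular protein genes and Jhamt were called, or 4, 2, 4 and 1 adjusted over the list alone. In the camera test, neuropeptides (adjusted p = 0.00346) and cuticular protein genes (adjusted p = 0.011) were shifted upward with the preset correlation, but not with an estimated correlation (adjusted p = 0.595 for both). The neuropeptide median was -0.17 and its mean 1.38, so median and test differed in sign. Degradation and transport genes had adjusted p = 0.379 with the preset and 0.595 with an estimated correlation, and their median of -0.11 and mean of 0.60 also differed in sign. Receptors had a median of -0.64 and adjusted p = 0.844 with the preset and 0.935 with an estimated correlation.

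Over all probes, limma called 576 higher and 6 lower in the CC-CA of both stages, the 6 being of 5 unnamed sequences. Leaving out replicate 1 or replicate 2 of the 4th instar CC-CA gave 347 and 333 higher, leaving out the clone set named caL gave 90, and restricting the fit to the 21952 probes well above background on all arrays gave 144. With slide as a fixed block, 471 probes were higher and 1 lower, and with slide as a random block 567 and 7.

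Enriched probes were also compared with stage calls. Of the 593 enriched probes, 108 (18.2%) were higher in the 4th instar and 22 (3.71%) lower, against 26.6 and 7.46 for independent lists of the same sizes. Both results share the 4th instar arrays. With no effect simulated, 0 probes were enriched, so that simulation gives no value for the overlap of the calls. At unadjusted p the simulated overlap was 1.57 on average against 0.0576 for independent lists, so sharing the arrays alone raised it. The shared pair could not be divided into sets of more than 1 array each, so the excess is not shown to go beyond that of the shared arrays.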

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

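The alternatives with normexp, without the clone set named caL, without probes 4-fold higher in another tissue, and without testis for the enriched probes were chosen after seeing the data, and the others before. Of named-gene values under the alternatives, 391 kept direction and side of the threshold, 48 lost their call, 4 gained one and 4 changed sign. Where no cause is named, the cause was not tested.

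With quantile normalisation 285 probes were enriched, all of them among the 593, and 0 were called higher and 0 lower between stages (smallest adjusted p = 0.186). The prior was then worth 1.52 degrees of freedom instead of 7.41, and the cause was not tested. The calls against single tissues were 2455 for prothoracic gland, 4476 for brain, 6573 for fat body, 6645 for midgut, 2017 for epidermis, 6772 for Malpighian tubule, 4622 for salivary gland and 2660 for ovary. The 3 CC-CA arrays had 70 probes lower than the other 9 tissues, and JHEH3 changed sign between stages (-0.11). Median differences of all probes moved by -0.14 between stages, -0.32 against salivary gland and -0.21 against Malpighian tubule.

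Scaling on the median of probes detected on all arrays gave 1 probe lower in the CC-CA than in all 9 tissues, and JHEH5 changed sign (0.0166). In the value table, 16378 probes differed from salivary gland and 22728 from testis, 2 were lower in the 3 against 9 comparison, and jhbp-wds30639 (-0.0919) and JHEH3 (-0.17) changed sign between stages. The value table moved the median difference by -0.30 between stages, -0.85 against salivary gland, 1.04 against testis, -0.46 against prothoracic gland, 0.39 against ovary, -0.31 against Malpighian tubule and 0.28 against epidermis.

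The filter to probes well above background on all 12 arrays, which left fewer probes to test and dropped those absent from any tissue, gave 174 enriched and 5 depleted probes, of which 132 enriched ones were shared with the 593. It gave 5128 calls against brain, 4128 against epidermis, 6808 against Malpighian tubule and 9221 against testis, 1521 lower in the 4th instar, and 144 higher and 2 lower in the 3 against 9 comparison. With a variance trend, 6 probes were depleted, 3162 were higher and 2009 lower in the 4th instar, and 10 were lower in the 3 against 9 comparison. With robust moderation, 3 were depleted, 15674 differed from fat body, and 2423 were higher and 1453 lower in the 4th instar. A threshold of 2 on the log2 scale left 2 probes lower in the 3 against 9 comparison. With normexp, 3 were depleted, 17772 differed from fat body and 1031 were lower in the 4th instar. A correction on the mean spot signal was planned and not run, since the files used here gave the median.

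Without the clone set named caL, fewer probes were tested. Then 117 were enriched, and the calls were 2720 for prothoracic gland, 3614 for brain, 4345 for fat body, 4604 for midgut, 3254 for epidermis, 4394 for Malpighian tubule, 3655 for salivary gland, 7405 for testis and 3373 for ovary. Between stages 650 were higher and 241 lower, and in the 3 against 9 comparison 90 were higher and 1 lower. Without probes 4-fold higher in another tissue, 463 were higher and 209 lower in the 4th instar.

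Pooling the CC-CA arrays of both stages as 1 group gave 256 enriched probes, all of them among the 593. Without testis 668 probes were enriched, and against only the 7 tissues of day 2 of the 4th instar 788 were. By fold alone, with no test, leaving out either 4th instar array gave 796 to 940 enriched probes against 809, and 1543 to 1909 higher against 1654 and 606 to 785 lower against 515 between stages. In the 3 against 9 comparison, leaving out a CC-CA array gave 333 to 440 higher and 1 lower. Leaving out a tissue gave 530 to 849 higher, and 2 lower without prothoracic gland, 11 without brain, 3 without midgut, 2 without Malpighian tubule, 11 without salivary gland and 11 without testis. With only the day 2 arrays of the 4th instar 520 were higher and 0 lower. With slide as a fixed block 1 was lower. In the group fit no paired analysis was possible, because only 1 group has 2 arrays.

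The camera tests of neuropeptides and cuticular proteins did not pass with an estimated correlation (adjusted p = 0.595 and 0.595), and passed with the mean of all probes of a gene, quantile normalisation and slide as a block (0.00165 to 0.0101 and 0.000279 to 0.0135). The share of spots well above background ran from 60.4% in fat body to 78.6% in testis, and folds of named genes over levels below that are given only as bounds. Medians of sets and lists, counts of calls and fitted log2 differences, plotted ones included, also used signals below that level without a bound, except where a floor is stated.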

Other observations

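Among the tests below, the splits of the 12 arrays and the comparison of brain-only sequences were written before their results were seen, and every other test was chosen after. The lists of sequences abundant in 1 tissue were also defined after the data were examined.

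Several peptide hormones had their highest level outside the nervous system. Bursicon reached 0.72 in testis against -4.41 in the 4th instar CC-CA. Its partner pburs was instead higher in the CC-CA (2.56 in the 4th instar) than in any of the 9 tissues. Of these only testis was well above background, at -6.29. In prothoracic gland, brain, fat body, midgut and epidermis no signal that low was well above background, so such a level could have been missed there. Kinin was highest in testis (2.17), and so was GPA-alpha (-1.93), while NPF1 was highest in midgut (2.14). These are single arrays without replicates, and the genes were chosen after their values were seen. Testis was of day 10 of the 5th instar on slide 3, and brain of day 2 of the 4th instar on slide 1. For the testis values, tissue, stage and slide cannot be told apart. Of 10 sequences that the array names only AB274988 to AB274997, 7 were enriched in the CC-CA and 0 were called between stages, a set chosen after the data were examined. AB274996 stood 231-fold above fat body, the next highest tissue.

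Salivary gland transcripts were higher in the 4th instar CC-CA, with a median log2 difference of 2.96 over 31 sequences (2.67 to 3.05 over the scalings). A difference between slides is argued against by the median of 3.103 on the slide that held both stages. Of these sequences, 83.9% lay within 1 log2 unit of their median ratio to salivary gland, which was 5.12% in the 4th and 0.609% in the 5th instar. Salivary gland RNA in the 4th instar preparations may account for them, and for binding protein transcripts most abundant in that gland. A stage difference in the CC-CA stays open and was not tested.

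Cuticular protein transcripts were present in the CC-CA, with 32 higher and 14 lower in the 4th instar. A slide difference is argued against, since 54.5% of all 99 tested members differed by 4-fold on the slide that held both stages, against 6.69% of tested probes, and so is 1 share of whole-epidermis RNA, since only 19.4% of 36 members abundant in epidermis lay within 1 log2 unit of their median ratio. That test, which did not select by CC-CA level, replaced 2 others, an undecided one (38.8% between bounds of 20% and 50%) and one on 41 genes selected as above background in the CC-CA (85.4%). A changed share of epidermal RNA like that of the epidermis array is argued against for the 14 lower genes. Epidermis-only sequences other than cuticular genes moved the other way (median 2.87, quartiles 1.08 to 4.85). That array was of day 2 of the 4th instar. No epidermis of the 5th instar was measured, so epidermal RNA of that stage stays open. A changed share may account for the higher genes, since 56.7% of those sequences were called higher against 4.49% of tested probes. Of the 32 higher genes, 26 were 4-fold more abundant in another tissue, a count over all other tissues that does not single out epidermis. A stage difference in the CC-CA stays open and was not tested.

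Neuropeptide transcripts had a median of -1.42 over 22 members as 4th minus 5th instar, with 3 called lower and 19 not called. Slides and dim signals are argued against by medians of -1.553 on 1 slide and -1.227 over the 14 members well above background on all 3 arrays. More brain RNA in the 5th instar preparation may contribute, since 152 brain-only sequences had a median of -1.075 (quartiles -1.50 to -0.67), in a set with a lower minimum level in brain (log2 0, not 2) and without neuropeptides that differs from the 97 of the report. Whole-brain RNA like that of the brain array is argued against, because the median ratio to brain lay 4.409 log2 units above its 10th percentile. That array was of day 2 of the 4th instar, and no brain of the 5th instar was measured. Eclosion hormone, 3.53 in brain, was not well above background in the 5th instar CC-CA. It was picked for its margin over all groups, CC-CA included, so its absence there is no evidence. Brain cells or nerve endings of some kinds only, and a stage difference, stay open and were not tested.

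In the comparison of 3 CC-CA arrays with 9 others, 1 of 100 drawn splits gave as many as 576 probes higher, the real one, and the highest other gave 77, in a split that held 2 CC-CA arrays. Every other split mixed tissues, so the real one was bound to stand out. The count shows only that the 3 arrays of 1 tissue belong together. Only probes higher in the 3 arrays were counted, so the splits do not bear on the balance of higher and lower probes. In the real split more probes were higher than lower, 576 against 6. Without the clone set named caL the counts were 90 and 1, which argues against that set as the source of the asymmetry. By a 2-fold margin with no test, each of the 9 other tissues had more probes above all groups than below all. Testis had 3090 and 1603, and brain 1218 and 270. Comparing 1 group with many may therefore produce some of the asymmetry. By that margin over the 9 other tissues the 4th instar CC-CA had 809 and 17, a more uneven split than any other tissue. Epidermis came nearest (1729 and 157). These counts are not alike, so the CC-CA cannot be ranked by them. The CC-CA was a mean of 2 arrays and was not set against the CC-CA of the other stage. Each other tissue was 1 array set against all groups. Probes named caL were 76.3% of the 809, against 14.7% (testis) to 58.2% (salivary gland) of those above all groups in the other tissues. The margin count differs in form from the fit of 3 against 9, so it does not settle the source.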
